A study of Mus musculus with 16 samples.

How the data were processed

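Gene expression was measured on Affymetrix Mouse 430A 2.0 arrays in mouse J1 embryonic stem cells grown, per the labels, on gelatin with serum and LIF. There were 16 arrays in 5 groups. The knockdown arm held 2 Tgif1 KD and 2 shControl arrays. The overexpression arm held 4 BirA control arrays, 4 arrays labelled Tgif1 OE and 4 arrays labelled Tgif2 OE. A Tgif2 knockdown is named in the series description and was not analysed here, because no such sample is among the 16. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

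The deposited values are log2 intensities per probe set, which the authors made with RMA per the submitters' processing notes; those notes also name limma for the Tgif2 samples, and the versions are not given in the sources used here. The values ran from 2.19 to 14.79. The column medians of the 4 Tgif2 OE arrays averaged 0.08 log2 above those of the other 12, and the column means 0.11 above. A difference of medians over 0.1 had been set as the point at which all columns would be quantile-normalized, so the deposited values were used throughout. In the comparisons that involve the Tgif2 OE arrays, changes of single genes are given relative to the median change of all genes unless named as deposited. The p-values, standard errors and calls beside them are those of the deposited changes. Counts after quantile normalization stand beside them.

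Of 22690 probe sets, 64 were controls, 20380 carried 1 gene symbol, 691 carried several and 1555 carried none. Symbols were compared with the 2016 annotation supplied with the reference; a gene number was found for 20351 probe sets and 0 symbols needed an update. Each of 12393 genes was represented by its probe set with the highest mean over the 16 arrays, and 4956 genes had more than 1. Detection calls were not used, and no gene was left out for low intensity. A single symbol does not exclude hybridization to close relatives of a gene.

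One linear model with a mean per group was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, with moderated tests and p-values adjusted by the Benjamini-Hochberg method over all genes of a comparison. The threshold was an adjusted p under 0.05. Values after ± are standard errors of a log2 fold change from this fit unless an SD is named. The comparisons were Tgif1 KD with shControl, the arrays labelled Tgif1 OE and those labelled Tgif2 OE each with BirA control, and the arrays labelled Tgif1 OE with those labelled Tgif2 OE. A contrast also tested the difference between the Tgif1 KD effect and the Tgif1 OE effect. With 2 arrays per group in the knockdown arm and 4 in the overexpression arm, the spread was pooled over the 5 groups, and the number of arrays limits the precision of every estimate.

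There were 22 fixed gene lists with 329 entries, of which 295 were measured; these were 312 distinct genes, 279 of them measured. The lists covered core and naive pluripotency, general ES cell genes, formative and primed pluripotency, trophectoderm, primitive endoderm, mesoderm and primitive streak, neuroectoderm, Nodal and TGF-beta targets, BMP targets, retinoic acid response, Wnt targets, Tgif-associated corepressors and Smads, Polycomb subunits, 2-cell-stage genes, germline genes, cell cycle, p53 targets, interferon response, ATF4 and unfolded protein response, and glycolysis and hypoxia. Markers of embryonic fibroblasts (feeder cells) and of blood cells stood for other cell types. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 22 lists. The adjusted p after a list's counts is from this test. The p with an estimated correlation is given beside each call that it ended. Counts of list members past the threshold are followed, as "list alone", by the counts when p-values are adjusted over that list only.

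The genes named were chosen by a rule. It takes Tgif1 and Tgif2; among genes whose groups do not overlap, the 5 with the largest rise and the 5 with the largest fall; up to 3 members of each list past the threshold with the largest change; and Pou5f1, Sox2, Nanog, Klf4, Esrrb, Zfp42, Cdx2, Gata6, T and Fgf5 in each comparison. It also takes up to 5 genes per direction called in a pair of comparisons, ranked by the smaller of the changes. T had no probe set with 1 symbol. The text names some of the list members only, and passed over most members whose call changed when 1 array was left out, even where their change was larger; that choice was made after the values were seen. Groups, tests, lists and this rule were fixed before the data were examined.

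Arrays that share a replicate number were compared across the groups of the overexpression arm. The deviations of such arrays from their group means correlated at 0.32 to 0.56 over 12 comparisons. An array's own number gave its best match in only 2 of 12, so these correlations do not show that the single numbers mark something shared. Replicates 1 and 2 resembled each other, as did replicates 3 and 4: within such array pairs r was 0.998 to 0.999, and between them 0.994 to 0.996. The root mean square difference was 0.12 to 0.18 log2 within the 6 pairs and 0.25 to 0.30 in the 12 comparisons between pairs. In the knockdown arm replicates correlated at r = 0.998 and the deviations of shared numbers at -0.004, so there the arrays share only a number. Their root mean square difference, 0.16 log2 in each group, lay within the range of the array pairs. The arrays of a knockdown-arm group may thus form only such a pair, and then do not show the spread between pairs. Results were therefore also computed with the replicate number as a block, with the array pair as a block (fixed or random), with the array pairs averaged, and within replicates 1 and 2 or 3 and 4 alone. The random block, the fixed pair block without averaging and pair means without a block were applied to the counts of genes only. Named genes and lists were recomputed with pair means and the pair as a block. The array pair settings average or block only the overexpression arm, and change the knockdown through the pooled spread alone. Fits of replicates 1 and 2 or 3 and 4 alone test against the spread within pairs, which was smaller than that between pairs. Their p-values and counts of genes therefore leave out the spread between pairs. The analyses by array pair were chosen after seeing the data.

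Other alternatives were quantile normalization, an equal median for each array, a trended and robust variance, removal of the dimmest 33.3% of genes, probe sets tested singly or averaged, only the compared groups in the fit, array weights, a minimum change of 1.5-fold, and each array left out in turn. Camera with an estimated correlation and fry were alternatives for the lists. A range of a list's adjusted p over alternatives covers the camera tests, with the estimated correlation among them, and leaves out fry. Where an array left out leaves its group with 1 array, that array is assumed to vary like the other groups. Every other split of 8 arrays into groups of 4 was tested in the overexpression arm. Log2 differences between 5′ and 3′ control probe sets of Gapdh and Actb gave a sign of RNA quality, compared with exact permutation tests in the overexpression arm. The exact tests within array pairs were chosen after seeing the data.

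The fits were tested on simulated data of 12393 genes with known changes. Of genes changed by 1.5-fold, 2-fold and 4-fold, the fit called 58.2%, 94.0% and 100% for the knockdown design, and 77.6%, 98.5% and 100% for the comparison of Tgif1 OE with BirA control. False calls were 4.00% and 7.07% of the calls. For Tgif2 OE with BirA control the shares found were 82.1%, 97.0% and 100%, with 3.63% false. Of simulated lists, camera found the 1 that had been shifted and called 0 others. The simulated noise was independent between genes and between arrays. It lacked the array pairs and the correlation between genes of the real data, so these shares need not hold there.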

Results

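Tgif1 and Tgif2 encode homeodomain proteins that repress transcription, in part by binding Smad proteins. The knockdown lowered the Tgif1 signal from 10.69 ± 0.04 log2 (SD, n = 2) on shControl to 7.29 ± 0.25 on Tgif1 KD arrays, which left 9.51% of the control signal (log2 change -3.39 ± 0.10, adjusted p = 3.88e-11). Tgif2 rose on the same arrays by 0.81 ± 0.09 log2 (1.60e-05). On the arrays labelled Tgif1 OE the Tgif1 probe set was lower, not higher, than on BirA control: 10.12 ± 0.10 against 10.69 ± 0.04 (SD, n = 4), a change of -0.58 ± 0.07 (5.52e-05). The Tgif2 probe set on the arrays labelled Tgif2 OE did not pass the threshold (9.37 ± 0.09 against 9.26 ± 0.08; 0.11 ± 0.07, adjusted p = 0.208). Tgif1 was lower there too (-0.42 ± 0.07, 4.57e-04). These are deposited changes, and relative to the median change of all genes on those arrays they were -0.01 for Tgif2 and -0.54 for Tgif1. Tgif2 fell on the arrays labelled Tgif1 OE (-0.45 ± 0.07, 1.86e-04). Whether these probe sets detect the transgenes is not known here, so the overexpression groups are named below by their labels.

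**Figure D1:**
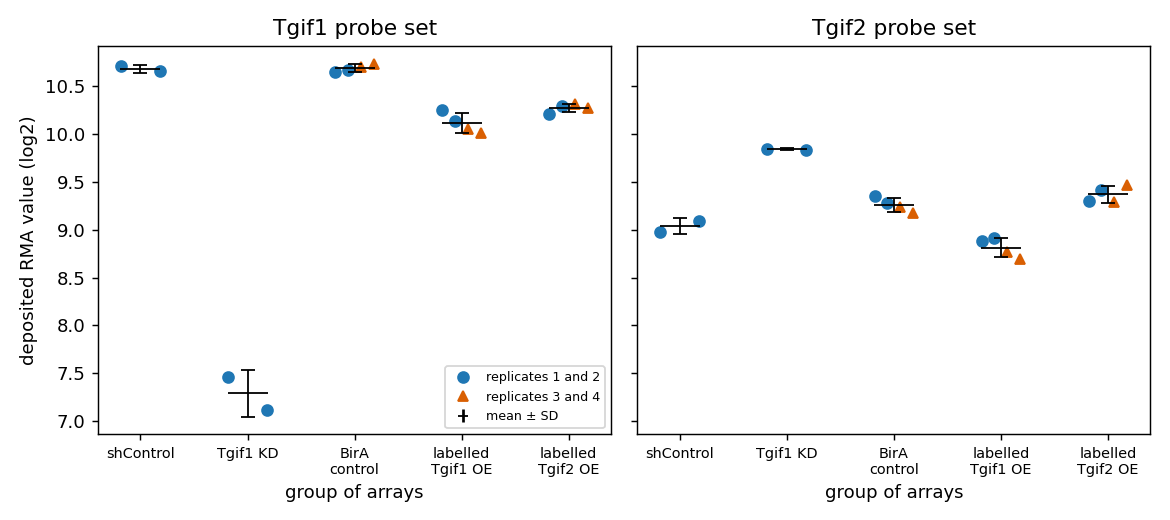
Tgif1 and Tgif2 probe set signal (log2) on each of the 16 arrays, with circles for replicates 1 and 2, triangles for replicates 3 and 4, and bars for group means with SD. The Tgif1 signal was low on Tgif1 KD arrays, and on the arrays labelled Tgif1 OE it lay below BirA control.

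In the Tgif1 knockdown, the 5 measured genes of the 2-cell stage were higher as a group, with 3 of them past the threshold. Usp17la, of a deubiquitinase family active in the early embryo, rose by 4.78 ± 0.15 log2 (5.81e-11), and Zfp352, a 2-cell-stage zinc finger gene, by 2.83 ± 0.15 (8.75e-09; n = 2 arrays per group throughout). The cyclin D genes Ccnd2 (-3.34 ± 0.23, 1.37e-07) and Ccnd1 (-1.06 ± 0.14) fell, while Ccnd3 rose (0.79). The other largest rises among genes whose groups do not overlap were AF067061 (3.70 ± 0.14), Gm20767 (3.64 ± 0.17), the Polycomb-associated Scml2 (2.98 ± 0.17) and the glutamate transporter Slc1a1 (2.94 ± 0.29). Besides Tgif1, the other largest falls were Rgs19 (-2.23 ± 0.10), which regulates G protein signalling, the cytoskeletal adaptor Pdlim7 (-2.06 ± 0.12, another of its probe sets gave 0.20) and Slc66a2 (-1.95 ± 0.11). Usp17la has near-identical copies in the genome, so its signal need not come from 1 gene.

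Of 10 listed 2-cell-stage genes 5 were measured. Zscan4c, Zscan4d, Zscan4f, Tdpoz3 and Tdpoz4 had no probe set with 1 symbol. Of the 5 measured 2-cell-stage genes, Usp17la, Zfp352 and Tcstv3 (0.69 ± 0.10) rose, and the other 2 did not pass the threshold (list alone: 3 higher, 0 lower, adjusted p = 1.05e-04, and adjusted p = 0.0151 with an estimated correlation). Of 11 p53 targets 5 rose and 0 fell (list alone: 6 and 0), among them Ccng1 (1.23 ± 0.19), Btg2 (1.08 ± 0.27) and Phlda3 (0.64). The call of Btg2 was lost without Tgif1 KD replicate 2 (adjusted p = 0.0649). The p53 list passed at 0.00536, but not with an estimated correlation (adjusted p = 0.524 with an estimated correlation). Those were the 2 lists past the threshold.

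The pluripotency genes moved both ways. Pou5f1 (0.17, adjusted p = 0.103), Sox2 (0.20, 0.226), Nanog (0.45, 0.209), Klf4 (0.09), Esrrb (0.55, 0.234) and Zfp42 (-0.04) did not pass the threshold. Of 20 core and naive genes 4 rose and 2 fell (list alone: 4 and 2, adjusted p = 0.116, range 0.0291 to 0.894 over 11 alternatives), with Pecam1 (1.01) and Fbxo15 (0.95) higher and Dppa3 (-1.28 ± 0.26) lower. Of 17 general ES cell genes 2 rose and 2 fell (list alone: 3 and 2, adjusted p = 0.964), including a rise of the Nodal co-receptor gene Tdgf1 (0.57) and a fall of Cdh1 (-1.11 ± 0.08), which encodes E-cadherin. Of 12 formative and primed genes 0 rose and 2 fell (list alone: 0 and 2, adjusted p = 0.116, range 0.0448 to 0.367), among them the DNA methyltransferase gene Dnmt3b (-0.61 ± 0.09). With fry the formative and primed list passed (1.30e-04). It and the core and naive list passed with the replicate block (0.0448 and 0.0291), and the core and naive list with array pair means and the pair as a block (0.0311). That last setting leaves the knockdown arrays as they are and changes only the pooled spread, here and for the lists below. Fgf5 did not pass (0.13).

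Among lineage genes, 6 of 18 primitive endoderm genes rose and 0 fell (list alone: 6 and 0), including the collagen IV genes Col4a1 (1.37 ± 0.16) and Col4a2 (1.13 ± 0.23) and the lineage factor Gata6 (0.59 ± 0.12). The list missed the threshold (0.0652), with a range of 0.00487 to 0.218 over 11 camera alternatives. It passed with fry (4.22e-05), with the mean of the probe sets (0.00487) and without Tgif1 KD replicate 1. Of 20 trophectoderm genes 2 rose and 2 fell (list alone: 2 and 2, adjusted p = 0.964), with Tfap2c at -1.02 and Cdx2 short of the threshold at -0.25. Counts were 1 higher and 2 lower for 16 mesoderm genes (list alone: 1 and 2, adjusted p = 0.964), with Eomes at 0.53. They were 1 and 2 for 13 neuroectoderm genes (list alone: 1 and 2, adjusted p = 0.578), with Neurod1 higher (2.66 ± 0.40) and Tubb3 lower (-1.17).

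None of the signalling lists passed the threshold with camera, while fry called Wnt targets lower and retinoic acid genes higher. Corepressors and Smads, a list that holds Tgif1 itself, were also called lower by fry. Nodal itself (0.63 ± 0.07) and Tgfbi (1.23 ± 0.26) rose and the Nodal target Lefty1 fell (-1.04), with 3 of 11 Nodal and TGF-beta targets higher and 1 lower (list alone: 4 and 1, adjusted p = 0.578). Of 12 BMP targets 2 rose and 1 fell (list alone: 2 and 1, adjusted p = 0.993), and the inhibitors of differentiation parted, Id4 rising (1.91 ± 0.17) and Id3 falling (-1.002). Tgm2 (2.02 ± 0.26, another of its probe sets gave -0.14) and the homeobox genes Meis1 (1.98 ± 0.18) and Meis2 (1.72 ± 0.25), of the retinoic acid list, rose (4 and 3 of 14, list alone: 5 and 3, adjusted p = 0.575). The Wnt antagonist gene Notum fell (-1.21), with 0 and 2 of 9 Wnt targets (list alone: 0 and 2, adjusted p = 0.368). Besides Tgif1 and Tgif2, Foxh1, a Smad partner in Nodal signalling, rose (0.63) among 14 corepressors and Smads (2 and 2, list alone: 3 and 4, adjusted p = 0.964). Bmi1 rose (2.19 ± 0.14) among 11 Polycomb subunits (2 and 4, list alone: 3 and 4, adjusted p = 0.964), whose median was -0.18 while the test's direction was up.

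Of 19 cell cycle genes 2 rose and 6 fell (list alone: 3 and 9, adjusted p = 0.0652, range 0.0179 to 0.405 over 11 camera alternatives), among the latter the replication gene Mcm2 (-0.58). The cell cycle list passed with fry (1.30e-04), with trended and robust variance (0.0251), with the mean of the probe sets (0.0179), with the replicate block (0.0291) and with array pair means and the pair as a block (0.0416). Of 14 ATF4 and unfolded protein genes 5 rose and 0 fell (list alone: 5 and 0, adjusted p = 0.0854, range 0.0291 to 0.871), with the asparagine synthetase gene Asns at 0.76, and the list passed in the last 2 of these alternatives (0.0291 and 0.0416). Of 14 glycolysis and hypoxia genes 3 rose and 1 fell (list alone: 3 and 1, adjusted p = 0.313), with P4ha1 at 1.36. Interferon genes gave 2 and 1 of 12 (list alone: 3 and 1, adjusted p = 0.964), with Oas1a at -1.02. Germline genes gave 1 and 1 of 10 (list alone: 1 and 1, adjusted p = 0.701). Fibroblast markers gave 1 higher, Vim (0.70), and 1 lower, Thy1 (-1.33), of 15 (list alone: 1 and 1, adjusted p = 0.964). Blood markers gave 0 of 8 either way (list alone: 0 and 0, adjusted p = 0.964). The test's direction was up for both, while the fibroblast mean was -0.09 and the blood median -0.02. The 5′ minus 3′ control difference was -0.21 for Gapdh and -0.64 for Actb on shControl arrays, and -0.09 and -0.51 on Tgif1 KD arrays. For both controls each Tgif1 KD array lay above each shControl array. A difference in RNA quality or labelling therefore cannot be told apart from the knockdown in this comparison. In all, 1552 genes were higher and 1594 lower, 3146 or 25.4% of 12393, with 268 and 127 of them changed at least 2-fold. Without shControl replicate 2 the count was 2012, and with 2 arrays per group the spread rests largely on the other groups.

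On the arrays labelled Tgif1 OE, formative pluripotency genes were higher as a group than on BirA control (n = 4 arrays per group). The naive factors Tbx3 (-1.63 ± 0.33, another of its probe sets gave -0.15), Tcl1 (-1.62 ± 0.15, 3.89e-06), Esrrb (-1.08 ± 0.22, 2.78e-03) and Nanog (-0.69 ± 0.17, 0.0103) fell. Sall2 (1.87 ± 0.12, 2.31e-07), the POU factor gene Pou3f1 (1.80 ± 0.18) and Cdh2, which encodes N-cadherin (1.29 ± 0.13), rose. Keratin genes Krt18 (2.86 ± 0.40), Krt8 (2.78 ± 0.36) and Krt19 (2.199 ± 0.47) also rose.

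Of 20 core and naive genes 0 rose and 11 fell (list alone: 1 and 14, adjusted p = 5.91e-08, adjusted p = 0.476 with an estimated correlation). Pou5f1 (-0.12, 0.119), Sox2 (-0.08, 0.575) and Klf4 (-0.39, 0.106) did not pass. Zfp42 passed at -0.35 (0.0152) but not without Tgif1 OE replicate 4 or BirA control replicate 1 (highest adjusted p 0.0547). Of 12 formative and primed genes 9 rose and 0 fell (list alone: 12 and 0, adjusted p = 4.24e-09, adjusted p = 7.30e-04 with an estimated correlation), while Fgf5 did not pass (0.24, 0.156). Among 17 general ES cell genes 3 rose and 6 fell (list alone: 3 and 8, adjusted p = 0.153), the latter including Sall1 (-0.55) and Dppa2 (-0.51).

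**Figure D2:**
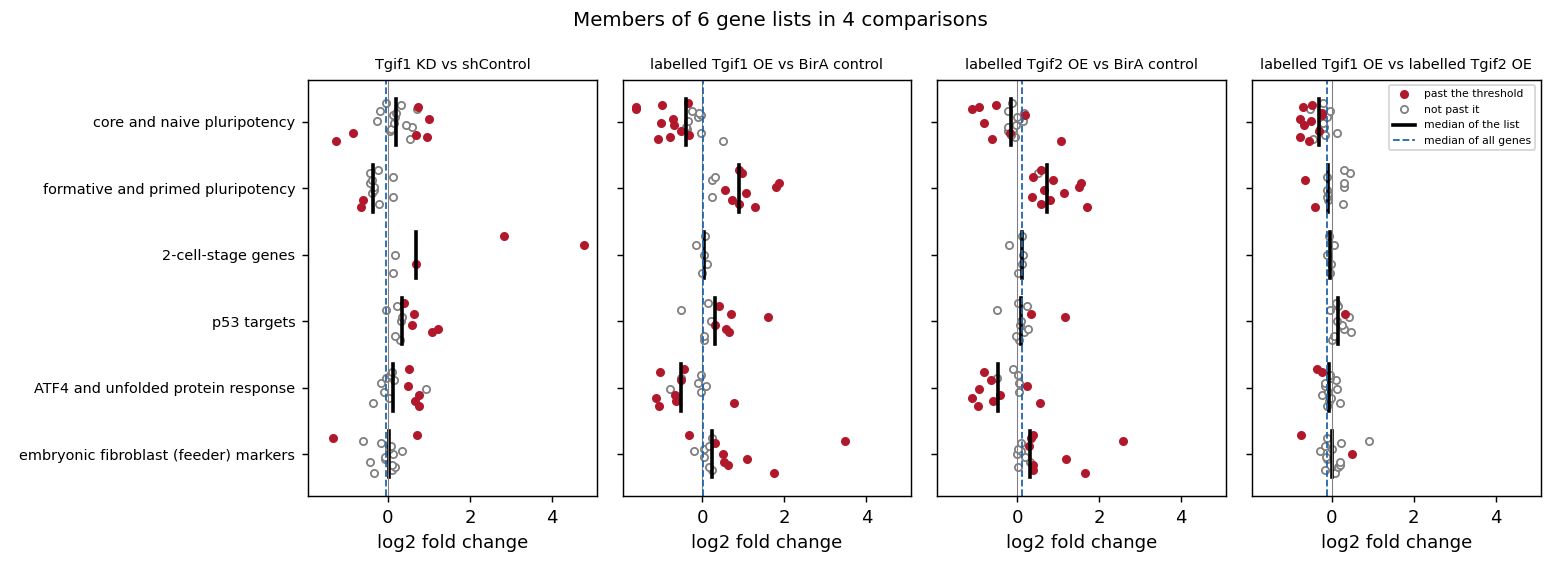
Log2 fold changes of the measured members of 6 gene lists in 4 comparisons, with filled red points past the threshold, open points not past it, black bars at list medians and dashed blue lines at the median of all genes. Formative genes lay above the median of all genes on the arrays labelled Tgif1 OE and Tgif2 OE, and 3 of 5 2-cell-stage genes rose in the knockdown.

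The largest rises among genes whose groups do not overlap were those of Tagln (3.48 ± 0.36, 1.14e-05), a smooth muscle actin-binding protein gene, the matrix gene Thbs1 (3.18 ± 0.38), the cytokine gene Ltb (3.05 ± 0.50) and the guanylate-binding protein genes Gbp2b (2.94 ± 0.29) and Gbp2 (2.92 ± 0.32). The largest falls were those of the stress gene Nupr1 (-2.03 ± 0.18), 2210409E12Rik (-1.998 ± 0.25), Timm8a2 (-1.78 ± 0.17), the galectin gene Lgals3 (-1.70 ± 0.08, 5.37e-09) and the microtubule-associated tau gene Mapt (-1.63 ± 0.10, another of its probe sets gave -0.18). Gbp2 and Gbp2b are close relatives, and their probe sets need not separate them.

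ATF4 and unfolded protein genes fell as a group, with 1 of 14 higher and 7 lower (list alone: 1 and 9, adjusted p = 9.38e-05, adjusted p = 0.476 with an estimated correlation), including Asns (-1.06 ± 0.12) and the pseudokinase gene Trib3 (-1.02 ± 0.07, 3.27e-07). Of 11 p53 targets 6 rose and 0 fell (list alone: 6 and 0, adjusted p = 0.00960, adjusted p = 0.520 with an estimated correlation), including Perp (1.59 ± 0.26) and Phlda3 (0.69). This call was lost without BirA control replicate 3 (0.0542) or replicate 4 (0.0627) and with replicates 1 and 2 alone (0.356). Its range over 17 alternatives was 1.44e-05 to 0.520. Fibroblast markers rose as a group, with 7 of 15 higher, including Tagln, the smooth muscle actin gene Acta2 (1.75, another of its probe sets gave 0.01) and Col5a2 (1.09), and 1 lower (list alone: 7 and 1, adjusted p = 0.00597, adjusted p = 0.476 with an estimated correlation). Without the dimmest 33.3% of genes that list missed the threshold (0.294, range over 17 alternatives 7.69e-04 to 0.476). Blood markers gave 0 of 8 either way (list alone: 0 and 0, adjusted p = 0.575). The 5′ minus 3′ difference for Gapdh was -0.17 against -0.08 on BirA control (exact p = 0.343, and 0.167 by exact test within array pairs), and for Actb -0.54 against -0.51 (exact p = 0.571, and 0.389 within pairs). For Gapdh it was lower by -0.17 in replicates 1 and 2 and by -0.01 in replicates 3 and 4.

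Of 20 trophectoderm genes 6 rose and 1 fell (list alone: 7 and 1, adjusted p = 0.0586, range 0.0123 to 0.534 over 17 alternatives). The list passed with fry (0.0108), without Tgif1 OE replicate 1 (0.0352) and without BirA control replicate 3 (0.0403). It also passed in replicates 1 and 2 alone (0.0123) or 3 and 4 alone (0.0351), and with array pair means and the pair as a block (0.0394). Cdx2 did not pass (0.51, 0.0547) and passed without Tgif1 OE replicate 1 (0.0216). Among 18 primitive endoderm genes 2 rose and 1 fell (list alone: 2 and 1, adjusted p = 0.550), with Dab2 at 0.73, the laminin gene Lama1 at -1.01 ± 0.06 and Gata6 at 0.07, short of the threshold. Bmp4 fell (-1.53 ± 0.13, 1.62e-06), the 1 of 16 mesoderm genes to pass (list alone: 0 higher, 1 lower, adjusted p = 0.575). The median of that list was 0.04 while the test's direction was down. The neural progenitor filament gene Nes rose (0.89) among 13 neuroectoderm genes (3 and 0, list alone: 3 and 0, adjusted p = 0.208).

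Nodal and TGF-beta targets parted, with Ccn2 (1.67 ± 0.16) and the corepressor gene Skil (0.60) among 3 of 11 higher, and 3 lower (list alone: 3 and 4, adjusted p = 0.961). Their median was -0.11, their mean 0.38 and the test's direction down. Id2 (1.28 ± 0.26, another of its probe sets gave 0.21) and Id3 (1.08 ± 0.13) rose among 12 BMP targets (3 and 3, list alone: 4 and 3, adjusted p = 0.799). The retinoic acid-binding protein gene Crabp2 rose (1.47 ± 0.21) and Tgm2 fell (-1.10, another of its probe sets gave 0.03) among 14 retinoic acid genes (2 and 1, list alone: 2 and 1, adjusted p = 0.799). The Wnt targets Sp5 (1.59) and Lef1 (1.05) rose (2 and 0 of 9, list alone: 2 and 0, adjusted p = 0.281). Counts were 2 and 2 of 14 corepressors and Smads (list alone: 3 and 2, adjusted p = 0.992). Polycomb counts were 0 and 3 of 11 subunits (list alone: 0 and 3, adjusted p = 0.281), whose median was 0.02 with a test direction of down. The 2-cell-stage list had 0 of 5 genes past the threshold either way (list alone: 0 and 0, adjusted p = 0.961).

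Germline genes Hormad1 (-1.21) and Dazl (-1.10) fell (0 and 3 of 10, list alone: 1 and 3, adjusted p = 0.474), as did Ccnd3 (-1.19 ± 0.12) among 19 cell cycle genes (0 and 2, list alone: 0 and 2, adjusted p = 0.416). Of 12 interferon genes 3 rose and 1 fell (list alone: 4 and 1, adjusted p = 0.656), with Bst2 at 0.67 and Irf9 at -0.64. Of 14 glycolysis and hypoxia genes 1 rose and 4 fell (list alone: 1 and 5, adjusted p = 0.182), with the glucose transporter gene Slc2a1 at 0.45 and Egln3 at -0.69. That list passed without BirA control replicate 3 (0.0364) and in replicates 1 and 2 alone (0.0123; range 0.0123 to 0.692 over 17 alternatives). In all, 1408 genes were higher and 1179 lower, 2587 or 20.9%, with 155 and 54 changed at least 2-fold. Replicates 1 and 2 alone gave 3241 genes and replicates 3 and 4 alone 3074, counts that leave out the spread between pairs. With the array pair as a random block 1419 genes passed, and with array pairs averaged 802, both chosen after seeing the data.

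The knockdown and the arrays labelled Tgif1 OE share no control arrays, and their changes ran in opposite directions more often than in the same one. Across genes r was -0.14 (rho -0.13), -0.18 with replicates 1 and 2 of the overexpression arm alone and -0.09 with replicates 3 and 4 alone. The 5′ minus 3′ control differences were higher on each Tgif1 KD array than on shControl. On the arrays labelled Tgif1 OE, relative to BirA control, they were -0.17 (Gapdh) and -0.07 (Actb) in replicates 1 and 2. In replicates 3 and 4 they were -0.01 and 0.01. For those labelled Tgif2 OE Gapdh gave -0.06 and -0.004 and Actb 0.04 and 0.08. Whether RNA quality or labelling contributed to the opposition was not tested. Of 1076 genes called in both (657 for independent lists), 728 or 67.7% changed in opposite directions and 348 in the same one. In detail, 405 genes were higher in the knockdown and lower on the arrays labelled Tgif1 OE (148 for independent lists), 323 the reverse (181), 218 higher in both (176) and 130 lower in both (152). Such opposition was not confined to the arrays labelled Tgif1 OE. Between the knockdown and the arrays labelled Tgif2 OE r was -0.16, and by deposited changes 302 genes were higher in the knockdown and lower on those arrays (104 for independent lists), 732 the reverse (458), 390 higher in both (446) and 58 lower in both (107).

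Genes lower in the knockdown and higher on the arrays labelled Tgif1 OE included Pdlim7 (-2.06 ± 0.12 and 1.18 ± 0.09), the calmodulin-like gene Calml4 (-1.66 ± 0.33 and 1.22 ± 0.24), the adenylate cyclase gene Adcy7 (-1.21 ± 0.17 and 1.17 ± 0.12), the tight junction gene Cldn6 (-1.15 ± 0.21 and 1.28 ± 0.15) and Vwa5a (-1.03 ± 0.27 and 1.11 ± 0.19). The reverse held for 2210409E12Rik (2.54 ± 0.36 and -1.998 ± 0.25), the endosomal gene Eea1 (2.26 ± 0.24 and -1.40 ± 0.17), Timm8a2 (1.63 ± 0.24 and -1.78 ± 0.17), Lgals3 (1.48 ± 0.11 and -1.70 ± 0.08) and the acetyl-CoA synthetase gene Acss1 (1.42 ± 0.17 and -1.51 ± 0.12). Another probe set each of Vwa5a (0.01) and Acss1 (-0.13) went the other way in the knockdown. On the arrays labelled Tgif1 OE another probe set each gave 0.04 for Adcy7, 0.14 for Vwa5a, -0.0058 for Acss1 and 0.05 for Slc66a2. Higher in both were the ubiquitin ligase gene Rnf128 (2.05 ± 0.31 and 1.83 ± 0.22), the p53-inducible gene Pmaip1 (1.96 ± 0.23 and 1.40 ± 0.16), Nefm (2.24 and 1.54), Irs1 (1.58 and 1.46) and Igdcc4 (1.42 and 1.49). Lower in both were Tgif1, Slc66a2 (-1.95 ± 0.11 and -0.98 ± 0.08), Hmces (-0.87 ± 0.14 and -0.82 ± 0.10), Itpka (-0.85 and -0.91) and Lgals9 (-0.72 and -0.55). The knockdown calls of Nefm, Irs1, Igdcc4 and Itpka were each lost without any 1 of the 4 arrays (highest adjusted p 0.0792, 0.148, 0.156 and 0.142). That of Vwa5a was lost without Tgif1 KD replicate 1 or 2 or shControl replicate 1 (0.0704), and that of Lgals9 without Tgif1 KD replicate 1 or either shControl array (0.225). The overexpression call of Nefm was lost without Tgif1 OE replicate 3 or 4 or BirA control replicate 4 (0.0723).

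**Figure D3:**
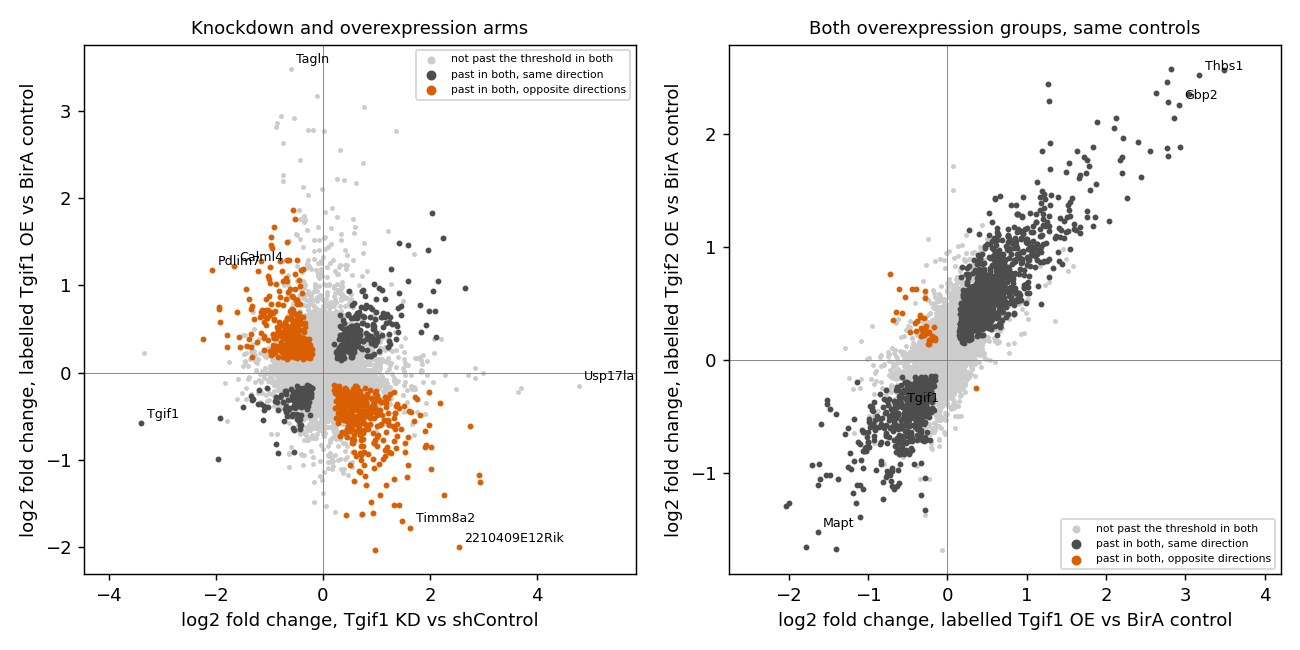
Log2 fold changes of 12393 genes on the arrays labelled Tgif1 OE against those in the Tgif1 knockdown and against those on the arrays labelled Tgif2 OE. Genes past the threshold in both comparisons are orange where they changed in opposite directions and dark where they changed in the same one.

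The difference between the knockdown effect and the effect on the arrays labelled Tgif1 OE passed the threshold for 3418 genes, 1607 with a higher and 1811 with a lower knockdown effect, and by at least 2-fold for 444 and 396. The largest positive differences were those of Usp17la (4.93 ± 0.19), 2210409E12Rik (4.54 ± 0.44), Slc1a1 (4.19 ± 0.35), the phospholipase gene Pla2g7 (4.08 ± 0.19) and AF067061 (3.88 ± 0.17). The largest negative ones were those of Tagln (-4.09 ± 0.63), Krt18 (-3.72 ± 0.69), Gbp2b (-3.71 ± 0.50), the myosin light chain gene Myl9 (-3.70 ± 0.49) and Ccnd2 (-3.57 ± 0.28). Among pluripotency genes the difference passed for Tcl1 (2.35 ± 0.26), Tbx3 (2.34 ± 0.58, another of its probe sets gave 0.22), Esrrb (1.63 ± 0.39, 5.29e-03), Nanog (1.14 ± 0.30, 0.0106), Dppa3 (-1.78 ± 0.31) and Cdh1 (-1.53 ± 0.10). It passed for the formative genes Sall2 (-2.31 ± 0.21), Pou3f1 (-2.14 ± 0.31) and Cdh2 (-1.95 ± 0.23). It also passed for Id4 (2.57), Id3 (-2.08), Tgm2 (3.12, another of its probe sets gave -0.17), Crabp2 (-2.44), Meis1 (2.21), Hormad1 (2.55), Bmi1 (2.54), Ccnd3 (1.98), Asns (1.82), Bmp4 (1.59), Lama1 (1.21), Tgif1 (-2.82) and Tgif2 (1.26). The calls of Pou5f1 (0.29, 0.0239) and Gata6 (0.52, 0.0168) were not stable. That of Pou5f1 was lost without any 1 of the 4 knockdown-arm arrays (highest adjusted p 0.0814), and that of Gata6 without replicate 2 of Tgif1 KD or shControl (0.0727). Sox2 (0.28), Klf4 (0.48), Zfp42 (0.31), Cdx2 (-0.76) and Fgf5 (-0.11) did not pass, and Cdx2 passed without Tgif1 OE replicate 1 (0.0357). The count was 4846 with replicates 1 and 2 of the overexpression arm alone and 4669 with replicates 3 and 4 alone.

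On the arrays labelled Tgif2 OE, formative genes were also higher as a group than on BirA control (n = 4 arrays per group). All changes of single genes in this comparison are relative to the median change of 0.12 log2 over all genes, while the p-values and calls beside them test the deposited changes. Cdh2 (1.58 ± 0.13, 8.71e-07), Sall2 (1.44 ± 0.12) and Pou3f1 (1.39 ± 0.18) were higher, and so were Krt18 (2.02 ± 0.40) and Krt8 (1.69 ± 0.36). Among genes whose groups do not overlap the largest rises were those of the contractile genes Myl9 (2.46 ± 0.29, 1.22e-05) and Tagln (2.46 ± 0.36), of Thbs1 (2.40 ± 0.38), the protease gene Prss23 (2.34 ± 0.43) and Gbp3 (2.33 ± 0.20). The largest falls were those of the plasminogen receptor gene Plgrkt (-1.80 ± 0.11, 1.39e-07), Eea1 (-1.79 ± 0.17), Timm8a2 (-1.78 ± 0.17), Mapt (-1.64 ± 0.10) and Zeb1 (-1.51 ± 0.11), a repressor of E-cadherin, another of whose probe sets gave 0.02 before the median was taken off.

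Of 12 formative and primed genes 11 were higher and 0 lower (list alone: 11 and 0, after quantile normalization 9 and 0, adjusted p = 3.41e-05, adjusted p = 0.00800 with an estimated correlation). Fgf5 (0.24, 0.0218) lost its call after quantile normalization (0.142) and without BirA control replicate 1 or 4 or Tgif2 OE replicate 1 (highest adjusted p 0.0621). Of 20 core and naive genes 2 were higher and 6 lower (list alone: 2 and 7, quantile 1 and 9, adjusted p = 9.30e-04, adjusted p = 0.938 with an estimated correlation), with Tcl1 at -1.04 ± 0.15 and Dppa3 at 0.95 ± 0.18. The call of this list was also lost with fry (0.219). Pou5f1 (-0.12), Sox2 (0.05), Nanog (-0.14), Klf4 (-0.22) and Zfp42 (-0.25) did not pass, though Zfp42 passed after quantile normalization (0.0273). Esrrb (-0.74, 0.0428) lost its call without BirA control replicates 1, 2 or 4 or Tgif2 OE replicates 3 or 4 (highest adjusted p 0.131). Of 17 general ES cell genes 5 were higher and 0 lower (list alone: 5 and 0, quantile 3 and 0, adjusted p = 0.870), including the adhesion genes Epcam (0.44 ± 0.10) and Cdh1 (0.40 ± 0.06).

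Of 14 ATF4 and unfolded protein genes 2 were higher and 7 lower (list alone: 2 and 7, quantile 1 and 7, adjusted p = 6.97e-05, adjusted p = 0.497 with an estimated correlation), with Asns at -1.08 ± 0.12. Of 20 trophectoderm genes 12 were higher, including the X-linked homeobox gene Rhox6 (1.60 ± 0.17), and 1 lower (list alone: 13 and 1, quantile 9 and 1, adjusted p = 0.0697, range 0.00823 to 0.938 over 17 alternatives). That list passed with fry (1.41e-04), after quantile normalization (0.00905) and with the mean of the probe sets (0.0167). It also passed without Tgif2 OE replicate 1 (0.0248) or 2 (0.0319), and in replicates 1 and 2 alone (0.0340) or 3 and 4 alone (0.00823). Cdx2 (0.45, 0.0213) lost its call after quantile normalization (0.0707) and without BirA control replicate 1 or 2 or Tgif2 OE replicate 3 or 4 (highest adjusted p 0.0694). Primitive endoderm counts were 7 and 2 of 18 (list alone: 8 and 2, quantile 3 and 2, adjusted p = 0.870), with Sparc at 0.41, Lama1 at -0.81 and Gata6 at -0.09, not past the threshold. Mesoderm counts were 5 and 2 of 16 (list alone: 5 and 2, quantile 3 and 2, adjusted p = 0.870), with Bmp4 at -1.14 ± 0.13 and Wnt3 at 0.58. Neuroectoderm counts were 5 and 0 of 13 (list alone: 6 and 0, quantile 4 and 0, adjusted p = 0.125), with Nes at 0.82 and Sox3 at 0.76 (another probe set of Sox3 gave 0.03 before the median was taken off).

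Of 12 BMP targets 8 were higher, including Id2 (1.16 ± 0.26) and Id3 (1.02 ± 0.13), and 1 lower (list alone: 8 and 1, quantile 7 and 1, adjusted p = 0.264). The other signalling lists gave 4 and 2 of 11 Nodal and TGF-beta targets (list alone: 4 and 2, quantile 2 and 3, adjusted p = 0.870), with Ccn2 at 1.01. They gave 2 and 0 of 9 Wnt targets (list alone: 2 and 0, quantile 1 and 0, adjusted p = 0.870), with Lef1 at 1.02, and 5 and 1 of 14 corepressors and Smads (list alone: 6 and 1, quantile 4 and 3, adjusted p = 0.870). Retinoic acid genes gave 5 and 2 of 14 (list alone: 5 and 2, quantile 3 and 4, adjusted p = 0.923), with Crabp2 at 1.12, Tgm2 at -1.23 (others of its probe sets gave 0.48 and 0.09 before the median was taken off) and the retinoic acid hydroxylase gene Cyp26a1 at 0.79. Their relative median was 0.09 while the test's direction was down. Of 11 p53 targets 2 were higher, including Perp (1.04 ± 0.26), and 0 lower (list alone: 2 and 0, quantile 1 and 0, adjusted p = 0.923). That list was down in replicates 1 and 2 alone (0.00452) and up in replicates 3 and 4 alone (0.0140), with a range of 0.00452 to 0.993 over 17 alternatives.

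Polycomb subunits gave 2 and 0 of 11 (list alone: 1 and 0, quantile 0 and 2, adjusted p = 0.870), and 2-cell-stage genes gave 0 and 0 of 5 (list alone: 0 and 0, quantile 0 and 1, adjusted p = 0.870). Germline genes gave 2 and 1 of 10 (list alone: 2 and 1, quantile 1 and 1, adjusted p = 0.870), with Hormad1 at -1.09. Cell cycle genes gave 5 and 1 of 19 (list alone: 7 and 2, quantile 0 and 4, adjusted p = 0.870), and interferon genes gave 3 and 2 of 12 (list alone: 4 and 2, quantile 2 and 3, adjusted p = 0.870; relative median 0.02, test direction down). Glycolysis and hypoxia genes gave 1 and 1 of 14 (list alone: 1 and 1, quantile 0 and 3, adjusted p = 0.142). The glycolysis and hypoxia list passed without BirA control replicate 3 (0.0194) and in replicates 1 and 2 alone (0.00452; range 0.00452 to 0.938 over 17 alternatives). Fibroblast markers gave 8 and 0 of 15 (list alone: 8 and 0, quantile 4 and 0, adjusted p = 0.243), with Acta2 at 1.54 (another of its probe sets gave 0.01 before the median was taken off) and Col5a2 at 1.07. Blood markers gave 1 and 0 of 8 (list alone: 1 and 0, quantile 1 and 0, adjusted p = 0.870). The 5′ minus 3′ difference was -0.12 for Gapdh (exact p = 0.514 against BirA control, and 0.167 by exact test within array pairs) and -0.45 for Actb (exact p = 0.229). For Actb it was higher than on BirA control in both pairs, by 0.04 in replicates 1 and 2 and 0.08 in replicates 3 and 4 (exact p = 0.0556 within pairs, the smallest that 36 arrangements can give). In all, 3559 genes were higher and 829 lower, 4388 or 35.4%, with 176 and 33 changed at least 2-fold. The share of higher genes among those called was 81.1%, and 51.5% after quantile normalization (1715 higher, 1616 lower). Replicates 1 and 2 alone gave 4646 genes and replicates 3 and 4 alone 4526, and with the array pair as a random block 2490 passed and with array pairs averaged 1699.

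The arrays labelled Tgif1 OE and Tgif2 OE shared many changes against the same 4 BirA control arrays. Higher in both, with deposited changes on the arrays labelled Tgif1 OE and Tgif2 OE, were Tagln (3.48 and 2.57, each ± 0.36), Thbs1 (3.18 and 2.52, ± 0.38), Myl9 (2.82 and 2.58, ± 0.29), Prss23 (2.77 and 2.46, ± 0.43) and Ms4a4d (2.63 and 2.37, ± 0.21). Lower in both were Nupr1 (-2.03 and -1.30, ± 0.18), 2210409E12Rik (-1.998 and -1.27, ± 0.25), Timm8a2 (-1.78 and -1.66, ± 0.17), Mapt (-1.63 and -1.53, ± 0.10) and Eea1 (-1.40 and -1.67, ± 0.17). In all, 1212 genes were higher in both (404 for independent lists), 526 lower in both (78.9), and 42 changed in opposite directions. After quantile normalization 959 were higher in both (194) and 741 lower in both (149). The 1738 shared calls in the same direction became 2038 with replicates 1 and 2 alone and 2177 with replicates 3 and 4 alone. Both of the latter counts rest on the smaller spread within pairs.

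Shared controls alone correlate a pair of comparisons, so unchanged groups were simulated against shared simulated controls. The noise was independent between genes and between arrays, and so lacked the array pairs of the data. Across genes r was 0.79 (rho 0.69) and the covariance 0.0747, while 100 simulated pairs of unchanged groups gave a mean r of 0.50 (highest 0.53), a mean covariance of 0.00639 (highest 0.00701) and at most 1 gene called in both. The covariance exceeded the simulated mean by 0.0683. With the BirA control arrays split so that each comparison used its own 2, over 6 splits, r was 0.53 to 0.75, the covariance 0.0586 to 0.0723 and the shared same-direction calls 980 to 1339. The 2 splits along the array pairs, which mix the comparison with the pair, gave the lowest r (0.53 and 0.57) and 99 and 150 opposite calls, against r of 0.73 to 0.75 and 13 to 22 opposite calls in the other 4.

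Compared directly, the arrays labelled Tgif1 OE had lower signal of Rhox6, Rhox5 and Rhox9 than those labelled Tgif2 OE (n = 4 per group). Changes of single genes here are relative to the median change of -0.10 log2 over all genes unless named as deposited, while the p-values and calls beside them test the deposited changes. The X-linked reproductive homeobox genes Rhox6 (-1.55 ± 0.17), Rhox5 (-1.38 ± 0.10, 7.08e-07) and Rhox9 (-1.33 ± 0.13), Aard (-1.29 ± 0.07, 1.25e-07) and the homeobox gene Hesx1 (-1.21 ± 0.18) had the largest falls among genes whose groups do not overlap. The largest rises were those of Plgrkt (1.72 ± 0.11, 7.08e-07), the homeobox gene Vax2 (1.19 ± 0.12), the nuclear envelope gene Sun2 (1.15 ± 0.07), Narf (0.97 ± 0.08) and Otub2 (0.93 ± 0.11, another of its probe sets gave -0.41 before the median was taken off). Tgif2 was lower (-0.45 ± 0.07, deposited change -0.56, 9.99e-05), and Tgif1 did not pass (deposited change -0.16, 0.137).

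Of 20 core and naive genes 0 were higher and 10 lower (list alone: 0 and 11, quantile 1 and 3), including Pecam1 (-0.68), Fbxo15 (-0.66 ± 0.10) and Tcl1 (-0.60 ± 0.15). Of 17 general ES cell genes the counts were 0 and 7 (list alone: 0 and 9, quantile 0 and 3), including Dppa2 (-0.44) and Sall1 (-0.39). Both lists passed at 0.0170, but not with an estimated correlation (adjusted p = 0.761 and 0.543 with an estimated correlation). Without Tgif1 OE replicates 3 or 4 or Tgif2 OE replicates 1 or 2, each left out alone, the core and naive list gave 0.108, 0.0878, 0.0733 and 0.182 (range 1.27e-06 to 0.761 over 17 alternatives). The general ES cell list gave 0.0777, 0.0610, 0.0624 and 0.104, and 0.0592 after quantile normalization (range 0.00295 to 0.543). Nanog (-0.56 ± 0.17, 0.0163) lost its call without Tgif1 OE replicate 4 (0.0510) and after quantile normalization (0.0760). Sox2 (-0.14, 0.0453) lost its call after quantile normalization (0.589) and without Tgif1 OE replicates 3 or 4 or Tgif2 OE replicates 1, 2 or 3 (highest adjusted p 0.130). Pou5f1 (-0.02), Klf4 (-0.19), Esrrb (-0.36), Zfp42 (-0.12), Cdx2 (0.04), Gata6 (0.14) and Fgf5 (-0.01) did not pass. Fgf5 passed without Tgif1 OE replicate 2 (0.0464).

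The p53 list was higher on the arrays labelled Tgif1 OE, with 1 of 11 members past the threshold and a relative median of 0.26 (list alone: 0 and 0, quantile 4 and 0, adjusted p = 1.16e-04, adjusted p = 0.543 with an estimated correlation). Its call was also lost with fry (0.0996). Trophectoderm genes gave 1 and 3 of 20 (list alone: 2 and 6, quantile 1 and 3, adjusted p = 0.797), with Tfap2c at -0.92 ± 0.13. BMP targets gave 0 and 5 of 12 (list alone: 0 and 5, quantile 0 and 3, adjusted p = 0.322), with Smad6 (-0.84 ± 0.15), Dlx5 (-0.55) and Smad7 (-0.44) lower. In replicates 3 and 4 alone the BMP list passed, lower (0.00523; range 0.00523 to 0.761 over 17 alternatives), as did the Nodal and TGF-beta list, higher (0.0297; range 0.0297 to 0.761). Other members past the threshold included Tubb3 (-0.58), Sox3 (-0.55, another of its probe sets gave 0.01 before the median was taken off), the mesoderm gene Bmp4 (-0.41), the germline gene Stk31 (-0.62) and Ccnd3 (-0.82 ± 0.12). Fibroblast markers gave 1 higher, Dcn (0.59), and 1 lower, Vim (-0.63), of 15 (list alone: 1 and 1, quantile 1 and 1, adjusted p = 0.128, range 0.0201 to 0.761 over 17 alternatives, past the threshold without Tgif1 OE replicate 1). Blood markers gave 0 and 2 of 8 (list alone: 0 and 2, quantile 1 and 0, adjusted p = 0.784). The other 15 lists had adjusted p-values of at least 0.322.

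In all, 279 genes were higher and 2160 lower on the arrays labelled Tgif1 OE, 2439 or 19.7%, with 4 and 24 changed at least 2-fold. After quantile normalization 1235 passed, 671 higher and 564 lower, so the higher share went from 11.4% to 54.3%. With the replicate number as a block 3688 genes passed. Replicates 1 and 2 alone gave 3032 and replicates 3 and 4 alone 2409. With the array pair as a random block 589 passed and with array pairs averaged 119.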

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

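The comparisons of array pairs, the tests of single arrays and the tests of what separates the pairs were chosen after the data were seen. Among 531 sets of 4 values (174 genes named by the rule, and the median, interquartile range and mean of each array, in the 3 groups of the overexpression arm), 17 or 3.20% had 1 array far from the other 3, where chance gives about 1 in 20. The measure is the gap of that array to its nearest neighbour over the range of the 4. On BirA control it was 0.934 for Dnmt3b (replicate 2, 11.93 log2 against a mean of 11.85 for the others), 0.843 for Gbp2b (replicate 1, 5.49 against 5.91), 0.873 for Sall1 (replicate 2, 6.78 against 6.58), 0.895 for Crabp2 (replicate 3, 6.16 against 6.04) and 0.929 for Mcm3 (replicate 4, 12.28 against 12.37). For the arrays labelled Tgif1 OE it was 0.851 for Rhox9 (replicate 3, 4.36 against 4.57), 0.838 for Meis1 (replicate 2, 3.55 against 3.78), 0.860 for Fgf5 (replicate 2, 4.68 against 4.14), 0.906 for Dab2 (replicate 2, 5.31 against 5.69), 0.842 for Stk31 (replicate 2, 5.54 against 6.05), 0.883 for Slc2a1 (replicate 3, 12.23 against 12.29), 0.864 for Zfp281 (replicate 2, 11.34 against 11.26) and 0.905 for Lgr5 (replicate 2, 4.37 against 3.79). For those labelled Tgif2 OE it was 0.865 for Tgm2 (replicate 4, 6.41 against 6.001), 0.880 for Sall1 (replicate 3, 6.46 against 6.61), 0.931 for Hesx1 (replicate 2, 7.09 against 6.58) and 0.866 for Smad6 (replicate 4, 7.01 against 6.86).

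Between replicates 1 and 2 and replicates 3 and 4, the effect on the arrays labelled Tgif1 OE differed for 485 genes (210 higher in replicates 3 and 4, 275 lower), and that on the arrays labelled Tgif2 OE for 751 (364 and 387). The p53 targets stood out: in replicates 3 and 4 the effect was higher for 3 of 11 on the arrays labelled Tgif1 OE (median 0.32; list adjusted p = 3.45e-06, adjusted p = 0.220 with an estimated correlation) and for 6 of 11 on those labelled Tgif2 OE (median 0.55; 4.78e-11, adjusted p = 0.0834 with an estimated correlation). The core and naive list was lower there, for 7 of 20 (median -0.15; 0.00123, adjusted p = 0.220 with an estimated correlation) and 8 of 20 (-0.25; 1.78e-05, adjusted p = 0.113 with an estimated correlation).

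Replicates 1 and 2 stood apart from replicates 3 and 4 in each group of the overexpression arm. A response to the overexpressed protein that differs between the pairs is argued against as the whole cause, since 3258 genes differed between the pairs of BirA control alone. A batch shared by the groups is a candidate explanation: the pair differences of BirA control correlated across genes with those of the arrays labelled Tgif1 OE at 0.521 and with those labelled Tgif2 OE at 0.535, where differences within pairs gave -0.004 and -0.158. A difference in RNA quality or labelling between the pairs is another candidate explanation, as part of such a batch or apart from it. In each group the 5′ minus 3′ differences were lower on both arrays of replicates 1 and 2 than on both of replicates 3 and 4, with a smallest gap of 0.0581. For Gapdh the means were -0.12 and -0.05 on BirA control, -0.29 and -0.05 on the arrays labelled Tgif1 OE and -0.18 and -0.05 on those labelled Tgif2 OE, and for Actb -0.55 and -0.47, -0.62 and -0.46, and -0.51 and -0.39. The exact p over the 3 groups was 0.00926 for each control, the smallest that 216 arrangements can give. A different state of the ES cells between the pairs cannot be told apart from a batch, because the core and naive list, with 15 of 20 members lower in replicates 3 and 4, gave 6.97e-09 but adjusted p = 0.0843 with an estimated correlation, and the labels name no culture for each replicate. No other biological explanation was tested.

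Among 2246 probe sets without exactly 1 gene symbol, which the gene comparisons leave out, 369 passed the threshold for Tgif1 KD against shControl, 266 for the arrays labelled Tgif1 OE and 596 for those labelled Tgif2 OE against BirA control, and 363 between the latter groups.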

How the results depend on the processing

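Alternatives by array pair, and replicates 1 and 2 or 3 and 4 alone, were chosen after seeing the data; all others were planned. Where no construction is named, the cause was not tested. A minimum change of 1.5-fold, a stricter rule, left 1337 genes for the knockdown, 697 for the arrays labelled Tgif1 OE, 819 for those labelled Tgif2 OE, 199 between these groups and 2075 for the difference of the Tgif1 effects. Leaving out 1 array, which lowers the number of arrays, gave 2012 to 2161, 2053 to 2372, 3750 to 4215, 1729 to 2121 and 2495 to 3405. The replicate block gave 4235, 3548, 5552, 3688 and 4496. The array pair as a block gave 4725, 4101, 6007 and, between the overexpression groups, 4444. With the array pair as a random block (correlation 0.554) the overexpression counts were 1419, 2490 and 589. Pair means, 2 values per group, gave 802, 1699 and 119, and with the pair as a block 2020, 3622 and 1167. A fixed pair block raised these counts with or without averaging, while averaging and a random block lowered them. For the knockdown, pair means with the pair as a block gave 4625. There, as for 4725, its arrays were neither averaged nor blocked, and only the pooled spread changed. Array weights gave 4735 for the knockdown. Between the overexpression groups, quantile normalization gave 1235 and an equal median 1103, since both remove the shift between these columns. Testing 20380 probe sets singly gave 3847 there and 5165 for the difference of the Tgif1 effects, with more tests run.

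The correlation of -0.14 between knockdown and Tgif1 OE changes ran from -0.155 to -0.119 with 1 array left out. It was -0.153 without the dimmest 33.3% of genes, -0.182 with replicates 1 and 2 alone and -0.0854 with replicates 3 and 4 alone. The 1738 shared calls of the overexpression groups ran from 1417 to 1746 with 1 array left out, were 2424 with the replicate block, and with split controls fell to 1006, 980, 996 and 992 in 4 of 6 splits, each comparison then having fewer control arrays.

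Lists past the threshold (2, 5, 3 and 3 in the order above) ran from 2 to 3, 4 to 6, 3 to 4 and 1 to 4 with 1 array left out. An estimated correlation, which widens the null, gave 1, 1, 1 and 0. Fry, which asks whether members shift in a common direction without setting them against other genes, gave 8, 9, 15 and 12. In the last 2 comparisons it therefore also takes up the shift of the Tgif2 OE columns. Of its knockdown calls 1, corepressors and Smads, holds Tgif1 itself. Fry also ended the call of the core and naive list on the arrays labelled Tgif2 OE (0.219). Between the overexpression groups it ended that of the p53 list (0.0996). For the knockdown the count was 1 without the dimmest 33.3% of genes, where the 2-cell-stage list had too few members for the test, 4 with mean probe sets, 6 with the replicate block and 5 with pair means and a pair block. For the arrays labelled Tgif2 OE it was 6 with replicates 1 and 2 alone and 5 with replicates 3 and 4 alone, and between the overexpression groups 5 with replicates 3 and 4 alone.

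For 174 named genes, 392 changes were recomputed to 4719 values. Of these, 4284 kept their side of the threshold, and their direction too unless neither value passed. Another 350 no longer passed, 63 newly passed and 22 turned, changing direction with at least 1 value past the threshold. Quantile normalization ended 40 calls and leaving out 1 array ended 77. Array pair means with the pair as a block ended 32 calls and added 10. Pair means without a block and the random pair block, which lowered the counts of genes, were not applied to the named genes or the lists. How far these calls hold against the spread between pairs is therefore not known here. Of 264 values from other probe sets of these genes 174 kept side and direction in that sense, 70 no longer passed and 20 turned. Those that turned are given here as deposited changes. In the knockdown these were Pdlim7 0.20, Tfap2a -0.12, Tgm2 -0.14, Atf4 -0.19, Vwa5a 0.0096 and Acss1 -0.13; on the arrays labelled Tgif1 OE, Tgm2 0.032 and Slc66a2 0.052; on those labelled Tgif2 OE, Zeb1 0.021, Tgfbi 0.34, Tgm2 0.48 and 0.087, Egln3 0.032 and Rnf2 -0.62. Rnf2 (adjusted p = 3.18e-05) was the 1 to pass in the other direction, and gave -0.015 after quantile normalization and -0.041 as the mean of its probe sets. Between the overexpression groups they were Otub2 -0.41, Sox3 0.013 and Dab2 -0.089, and for the difference of the Tgif1 effects Mybl2 -0.45, Tgm2 -0.17 and Pcgf6 0.015. Relative to the median change Zeb1, Egln3, Dab2 and the second value of Tgm2 on the arrays labelled Tgif2 OE kept the direction of the main probe set. Signal over background was not examined, since detection calls were not used, so dim genes are limited by a floor not measured here.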

Other observations

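The tests in this part were chosen after the results were seen, except that of bins of signal and that of the hybridization controls. Between the array pairs of the overexpression arm, averaged over its groups, 5283 genes differed, 2921 higher and 2362 lower in replicates 3 and 4. The genes named here were chosen after their values were seen. Naive factors were lower in replicates 3 and 4: Tbx3 by -0.87, Esrrb by -0.65, Nanog by -0.51 and Klf4 by -0.44 log2, with a list median of -0.28. Glycolysis and hypoxia genes were lower for 9 of 14 (median -0.24; 8.17e-04, adjusted p = 0.212 with an estimated correlation), among them Pfkl (-0.64) and Pkm (-0.48), and ATF4 and unfolded protein genes for 8 of 14 (4.35e-04, adjusted p = 0.166 with an estimated correlation). The keratin genes Krt19 (1.31), Krt18 (1.09) and Krt8 (0.91) were higher, with 9 of 20 trophectoderm genes (0.0153, adjusted p = 0.0941 with an estimated correlation), as were the fibroblast markers Tagln (0.97) and Acta2 (0.88; 9 of 15; 0.0286, adjusted p = 0.141 with an estimated correlation). Several of these genes also differed between the arrays labelled Tgif1 OE and BirA control, groups that hold both pairs alike.

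Families of genes with a shared symbol stem, 395 of them, were tested like the lists. Guanylate-binding protein genes (Gbp) rose as a family on the arrays labelled Tgif1 OE, 4 of 6 past the threshold with a median of 1.28 (0.00959, adjusted p = 0.936 with an estimated correlation), and so did the matricellular Ccn genes, 3 of 5 (0.0356, adjusted p = 0.936 with an estimated correlation). Armcx genes were higher there than on the arrays labelled Tgif2 OE, 2 of 5 (0.0230, adjusted p = 0.998 with an estimated correlation). Between the control groups of both arms, shControl against BirA control, 2619 genes differed, 1689 higher and 930 lower on shControl.

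Of the 35 splits of 8 arrays into groups of 4, only the real one reached its count in each comparison: 1 of 35 for the arrays labelled Tgif1 OE (2587 genes, highest other split 706), 1 of 35 for those labelled Tgif2 OE (4388, highest other 1271) and 1 of 35 between these groups (2439, highest other 1871). In each the highest other split was the one along the array pairs, so the pairs are a structure of these samples and their arrays are not interchangeable with the others. With the array pairs as units there are 3 splits, too few for a share under 0.05, and the highest other counts among them were again 706, 1271 and 1871.

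On the arrays labelled Tgif2 OE 3559 genes were higher and 829 lower than on BirA control. A separate normalization of those arrays is a candidate explanation: the lowest of their column means, 6.88, lay 0.0800 above the highest of the other 12. An offset common to dim and bright genes is in line with that, the median change lying between 0.100 and 0.135 in each of 10 bins of signal. A broad rise of transcripts in these cells stays open. RMA sets arrays normalized together to a common distribution, so it would hide such a rise rather than show it as this offset. The counts of higher and lower genes therefore cannot decide it. Such a rise was predicted to leave the spiked hybridization controls in place, which holds only where normalization does not move them. These 18 probe sets differed by 0.134 with a standard error of 0.107. That lies past the bound of 0.1 set beforehand for excluding such a rise, but by less than the standard error, which is too wide to tell.

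The Tgif1 probe set was lower, not higher, on the arrays labelled Tgif1 OE than on BirA control. Exchanged labels of these groups are argued against, since shControl lay 1.45 times as far from the arrays labelled Tgif1 OE as from those labelled BirA control (root mean square 0.45 and 0.31 log2; 1.41 to 1.49 with each of 10 arrays left out). Lowered Tgif1 function as the main source of the changes there is argued against by the correlation of -0.140 with the knockdown changes. That r was weak, and it was -0.162 for the arrays labelled Tgif2 OE. RNA quality or labelling, which cannot be told apart from the knockdown, may also have contributed to it. A smaller part of lowered function is therefore not excluded. A probe set outside the transgene, with a fall of the cells' own transcript, may explain it, but the Tgif1 fall of -0.42 (deposited change) on the arrays labelled Tgif2 OE does not decide this, since the position of the probe set relative to the transgene is not known here. The design names overexpression of Tgif1 as the biological difference, which these probe sets leave untested.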
